A study of Homo sapiens with 4 samples.

How the data were processed

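RNA of STS26T cells with an shRNA against ENG (shENG, replicates 1 and 2) or a scrambled shRNA (shControl, replicates 1 and 2) was measured by RNA sequencing. Per the labels' protocols, cells were grown with 10% fetal bovine serum, infected at a multiplicity of infection of 10 with polybrene at 8 µg/ml, and selected with puromycin at 1 µg/ml from 48 h after infection. Also per the labels, libraries were made from 1 µg of total RNA with a TruSeq RNA kit and sequenced on an Illumina HiSeq instrument, and the mean RNA integrity number was 9.65. The labels name the molecule as polyA RNA. The number of hairpins, their sequences and the strandedness of the libraries are not given in the sources used here.

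The authors deposited 1 table of FPKM values for all 4 libraries, with 1 value per gene symbol and library. The submitters' processing notes name FastQC 0.10.1, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.1.9, Cufflinks 2.2.1 and Cuffnorm, and the genome build hg19 (GRCh37). Their roles, order and settings, the annotation and how libraries were scaled to each other are not given in the sources used here. MIR4461 alone held 36.5% to 38.7% of each library's summed FPKM, and short noncoding RNA genes together held 46.3% to 48.0%. The cause was not tested; FPKM divides by a length, which can inflate genes shorter than a sequenced fragment, and reads of another source can map to such a locus. The sums were 1091839 (shENG 1), 1121380 (shENG 2), 1134981 (shControl 1) and 1141722 (shControl 2). FPKM carry no counts, so absolute depth is unknown and no counting interval is given. Ratios of values below 0.3 FPKM between libraries were taken as an inverse sign of relative depth, which the unknown scaling between libraries also affects.

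Samples were grouped by their titles. Before the data were examined, the test, the gene lists, the rule for named genes and the alternatives were fixed. Values were taken as deposited, as log2(FPKM + 1). Fold changes are on this scale, which understates the change of genes at low levels; ratios given as "-fold" are of mean FPKM. Genes needed a mean of at least 1 FPKM over the 4 libraries (11748 genes), and 290 short noncoding RNA genes among them, recognised by the form of their symbols, were left out, because their FPKM can depend on a length below that of a fragment. Short RNA genes with other symbols, such as SNAR-E and RPPH1, stayed in the test and carry the same uncertainty. The remaining 11458 genes were tested with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend, 2 residual and 5.48 prior degrees of freedom, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The median standard error of a log2 fold change was 0.0675. The words rose and fell are used for genes past this threshold.

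For the text, genes were named by these rules: ENG; the 12 genes with the largest fold change in each direction among those past the threshold whose groups did not overlap, without clone identifiers or symbols that join several genes; and up to 4 members per list past the threshold with the largest change, or the most abundant member where none passed. This gave 120 genes. Further list members are named as examples, and those were chosen after their values were seen. In all, 31 gene lists were fixed, for signalling (BMP, TGF-β, MEK/ERK, NF-kB, YAP, Notch), secreted factors, matrix and adhesion, cell cycle, stress, metabolism, interferon response and antigen presentation, lineage and other cell types, ribosomal proteins and histones. The 27 lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, each adjusted over the lists. Camera at an estimated correlation takes its p-values from the 2 residual degrees of freedom, so it has little power here. Adjusted p-values given for lists are from camera unless fry is named. An exact two-sided permutation test was run for ENG.

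The gene test was tested on simulated data drawn for 11447 genes from the spread of the shENG and shControl libraries, with 200 genes changed in each of 5 runs. It recovered 51.2% of genes changed 1.25-fold, 94% of those changed 1.5-fold, 99.6% of those changed 2-fold and 100% of those changed 3-fold, and 6.00% of its calls were false. Camera recovered a list of 30 genes shifted by 0.3 on the log2 scale in 5 of 5 runs and called 0 of 150 unshifted lists. In both simulations the spread was measured on the log2(FPKM + 1) scale but added on the log2 FPKM scale. Noise was therefore too small at low levels, and recovery can be overstated there. The gene test was simulated with 200 changed genes per run and no trend shared across genes, so its rates may not hold here. Genes were simulated independently, so this does not give the rate of false calls for lists whose genes vary together.

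To look for traces of unintended targets, the presence of each 7-base word in the 3′ UTR was tested against the log2 fold change with a two-sided z test of means across genes, which treats genes as independent, in Python 3.11.15 (NumPy 2.4.6, SciPy 1.17.1), after 3′ UTR length and GC content were taken out. Of the tested genes, 94.3% were matched by symbol, or by a RefSeq synonym, to a transcript of GENCODE release 29. The 10445 genes with a 3′ UTR of at least 50 bases were searched for the 16352 words held by at least 20 genes, with Bonferroni correction. Words held by many genes and given a simulated shift of 0.06 on the log2 scale were recovered in 10 of 10 runs, and 1 of 10 runs without one gave a false word. Smaller shifts and rarer words were not simulated. That annotation is on another genome build than the deposited table, so no coordinates are given. Figures were drawn with matplotlib 3.10.9.

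Alternatives to single choices were pseudocounts of 0.1 and 0.5, no filter on level, a mean of at least 5 FPKM, quantile normalization, median centring, no intensity trend, robust variance, keeping short noncoding RNA genes, a replicate block, limma treat against a fold of 1.5, and leaving out each library. Removing a trend on transcript GC content, and leaving out genes with a leading 7-base word, were added after the data were seen. Reads shared between gene copies could not be separated, and raw reads were not used here.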

Results

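RNA was sequenced from STS26T cells, an established human cell line of malignant peripheral nerve sheath tumour (MPNST), a sarcoma of the Schwann cell lineage. The cells carried a lentiviral short hairpin RNA (shRNA) against ENG (shENG, 2 libraries) or a scrambled hairpin (shControl, 2 libraries). ENG encodes endoglin, a co-receptor for ligands of the TGF-β family that is best known from endothelial cells. Cells were infected at a multiplicity of 10 and selected with puromycin at 1 µg/ml from 48 h on. The comparison asks which transcripts differ in MPNST cells when ENG is silenced. The expression table listed 23284 gene symbols in FPKM, fragments scaled to transcript length and library size, without coordinates. Between 16429 genes (shControl 2) and 16703 genes (shENG 1) had a value above 0. The table held no read counts, so absolute depth was unknown and no counting interval could be given. Ratios of low values to those of shControl 1 reflect relative depth inversely, together with the scaling between libraries, which is not known. They peaked at 0.997 for shENG 1, 0.976 for shENG 2 and 0.987 for shControl 2. Across tested genes, log2 values correlated at Pearson's r of 0.996 between the shENG libraries, 0.997 between the shControl libraries and 0.989 across the groups. Genes are not independent replicates in these correlations. Nothing in the labels says that replicates came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical.

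ENG itself fell. Its level was 3.68 and 4.38 FPKM in the shENG libraries and 13.6 and 15.1 FPKM in the shControl libraries. The means were 4.03 ± 0.50 FPKM (SD, n = 2) and 14.3 ± 1.03 FPKM (SD, n = 2), so 28.1% of the control level was left. The log2 fold change was -1.61 (SE 0.0901, limma, adjusted p = 0.000150). An exact two-sided permutation test of 2 libraries against 2 gave p = 0.333, the smallest value that its 6 arrangements allow. The receptor genes TGFBR2 and BMPR1A did not pass the test, while TGFBR3, which encodes the co-receptor betaglycan, rose from 0.864 to 1.43 FPKM (log2 fold change 0.38). TGFBR2, the type II TGF-β receptor, averaged 50 FPKM in shENG and 47.6 FPKM in shControl, and the BMP receptor BMPR1A averaged 15.8 and 13.9 FPKM. ACVRL1, the receptor that endoglin assists in endothelial cells, averaged 0.0175 FPKM in shENG and 0.0271 FPKM in shControl and was too low to be tested.

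Many genes differed between the groups, most of them by little. The genes furthest up included MEST, an imprinted gene, CD69, an activation antigen of lymphocytes, and NEDD9, a scaffold protein of integrin signalling. Those furthest down, besides ENG, included MAPRE1, which encodes the microtubule plus-end protein EB1, the cytokine gene IL24, and ID1 and ID3, inhibitors of basic helix-loop-helix factors. Of 11458 genes tested, 1544 rose and 2043 fell (limma, Benjamini-Hochberg adjusted). The median absolute log2 fold change of these 3587 genes was 0.31, a 1.24-fold change. The mean FPKM differed at least 2-fold for 128 of the risen and 32 of the fallen genes. The groups did not overlap for 68.6% of tested genes, against 33.3% by chance for a single gene. All genes share the same 4 libraries, so a library-wide difference, such as the trend on GC content below, can separate many at once. Tested against a fold of 1.5 (limma treat), 19 genes rose and 10 fell. Leaving out shENG 1 gave 728 higher and 1110 lower genes, and leaving out shENG 2 gave 806 and 1062.

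**Figure D1:**
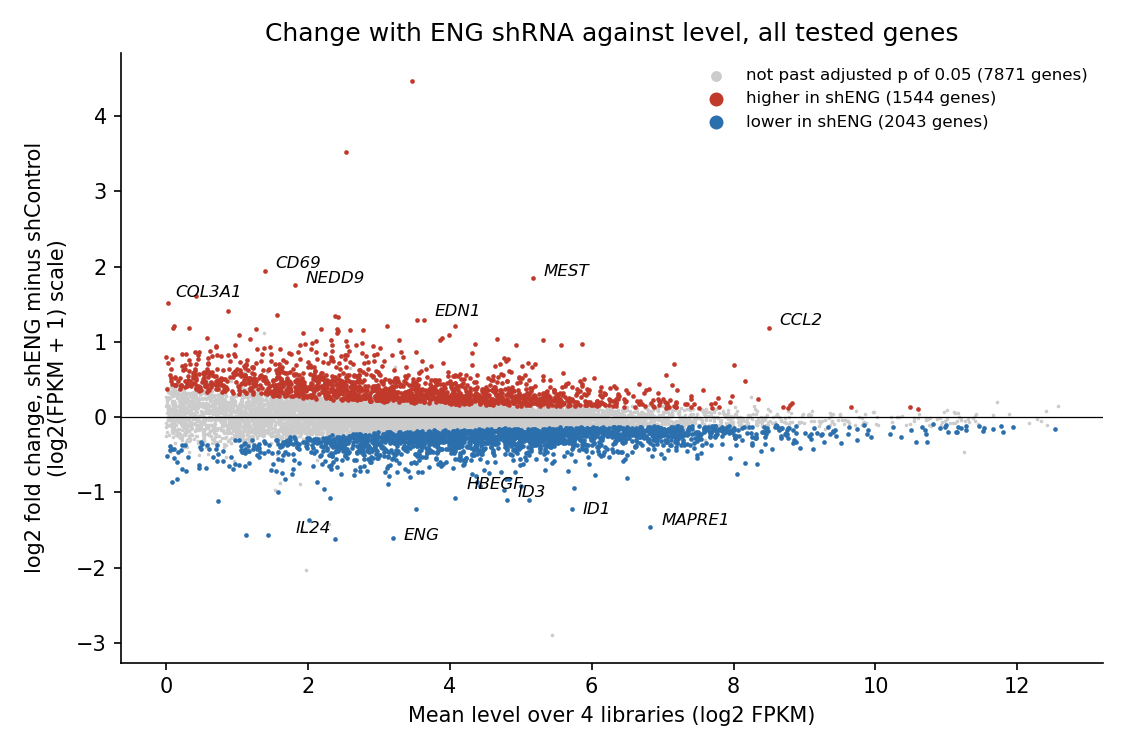
Log2 fold change of each tested gene (shENG minus shControl, on the log2(FPKM + 1) scale) against its mean level over the 4 libraries (log2 FPKM), with the 1544 higher genes in red, the 2043 lower genes in blue and other genes in grey. ENG lies at -1.61 and MAPRE1, at a higher level, at -1.46.

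MEST rose from 15 ± 0.40 FPKM (SD, n = 2) to 56.8 ± 2.33 FPKM (SD, n = 2), a log2 fold change of 1.85. CD69 had a log2 fold change of 1.95 and rose from 0.492 to 4.76 FPKM. NEDD9 had a log2 fold change of 1.76 and rose from 1.06 to 5.97 FPKM. FRZB, a secreted antagonist of Wnt ligands, had a log2 fold change of 1.62, and the fibrillar collagen gene COL3A1 of 1.52, both from control means below 0.2 FPKM. EDN1, which encodes the vasoconstrictor endothelin-1, rose 2.67-fold to 18.0 ± 2.22 FPKM (SD, n = 2). CD70, the ligand of the lymphocyte receptor CD27, rose 2.66-fold to 17 ± 0.33 FPKM (SD, n = 2). The glutamate transporter gene SLC1A1 rose 3.85-fold, the engulfment receptor gene MEGF10 3.17-fold and the transcription factor gene MSC 3.13-fold. LYPD6B rose to 2.76 and 3.43 FPKM from 0.900 and 0.232 FPKM, so its fold depends on the control library used. SNAR-E, a small RNA that binds the protein NF90 and has near-identical copies in the genome, was at 15.7 and 28.5 FPKM in shENG and was listed at 0 in both control libraries. Its value is uncertain because reads can be shared among the copies and because FPKM of so short an RNA depends on the length used.

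MAPRE1 fell from 167 ± 1.46 FPKM (SD, n = 2) to 60.2 ± 0.0076 FPKM (SD, n = 2), a log2 fold change of -1.46 (SE 0.0378, limma, adjusted p = 7.19e-06). IL24 fell from 6.29 to 1.82 FPKM (log2 fold change -1.37). C1D, whose product works with the nuclear RNA exosome, fell from 47.9 to 21.7 FPKM (log2 fold change -1.10). DDIT4, an inhibitor of mTORC1 induced by stress, fell from 16.5 ± 1.9 to 6.51 ± 0.19 FPKM (SD, n = 2). HBEGF, a ligand of the EGF receptor, fell from 23.3 ± 1.59 to 10.5 ± 0.05 FPKM (SD, n = 2). The fallen genes with the largest log2 fold changes also included RPPH1 (-1.63), RNF5 (-1.56), C15orf63 (-1.57) and HIST1H2BC (-1.12), and these 4 are uncertain. RPPH1 is the RNA of RNase P, is short and lacks a poly(A) tail. RNF5 shares sequence with the pseudogene RNF5P1, and their summed FPKM was 27.4 ± 0.13 in shENG and 26 ± 2.46 in shControl (SD, n = 2). C15orf63 was at 1.93 and 7.39 FPKM in the control libraries, and its overlap with neighbouring genes leaves its level open.

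**Figure D2:**
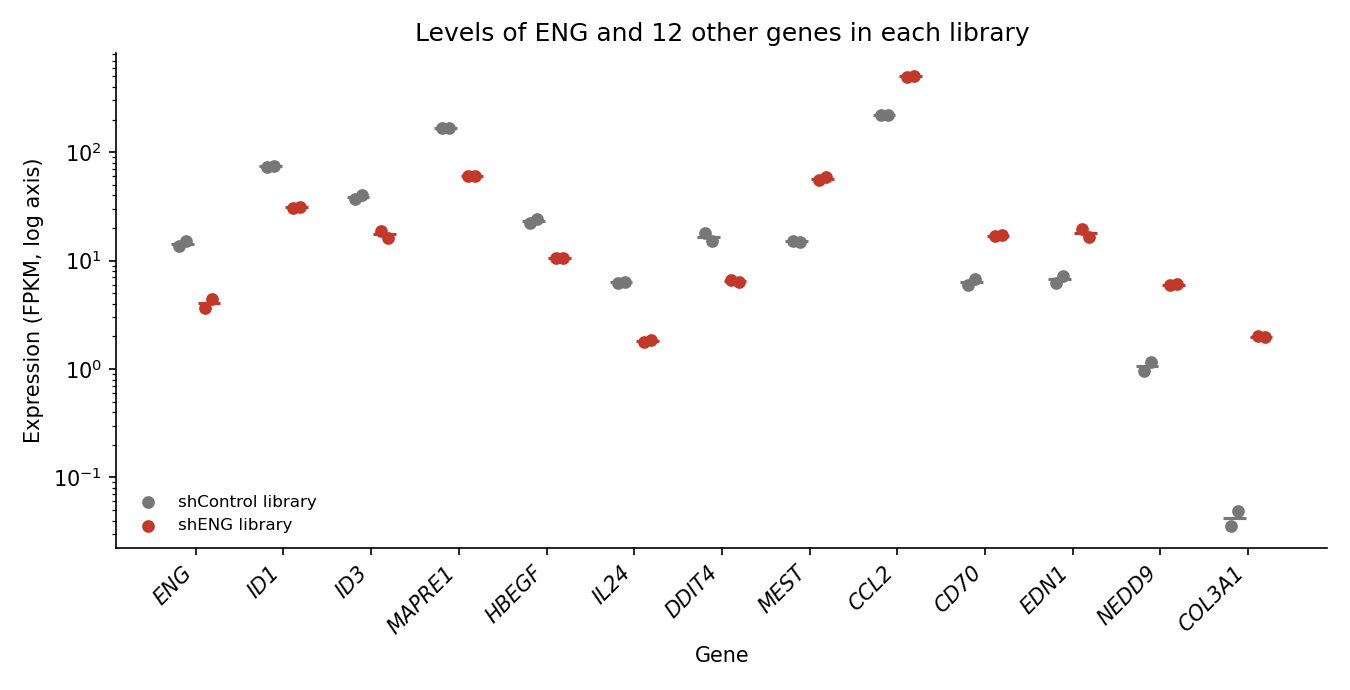
FPKM (log axis) of ENG and 12 other genes in each library, with shControl libraries in grey, shENG libraries in red and horizontal lines at the group means of 2 libraries. For each gene, both red points lie on 1 side of both grey points, as for CCL2 with means of 501 and 219 FPKM.

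Among BMP and SMAD1/5 target genes, ID1 and ID3 fell and other members rose. ID1 fell from 74.0 ± 0.78 to 31.1 ± 0.41 FPKM (SD, n = 2) and ID3 from 38.6 ± 1.93 to 17.4 ± 1.82 FPKM (SD, n = 2), log2 fold changes of -1.23 and -1.11. The transcription factor gene GATA2 (-0.52) and HES1 (-0.30) also fell. SMAD6, an inhibitor of BMP signalling, rose (0.69), as did MSX2 (0.35), BAMBI (0.29) and the BMP antagonist gene NOG (0.21). Of 14 tested members, 4 rose, 4 fell and 6 did not pass; adjusted over the list alone, 5 rose and 4 fell. Their median was 0.10 (0.0625 without shENG 1 and 0.0306 at 5 FPKM or more), their mean was -0.07 and fry pointed down, so these differ in sign. The camera test gave adjusted p = 0.865.

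TGF-β and SMAD2/3 target genes rose as a list, with 11 of 29 members up, 1 down and 17 not past the test. The camera test of the list gave adjusted p = 0.000395, and adjusted p = 0.348 with an estimated correlation. Adjusted over the list alone, 12 rose and 1 fell. NEDD9 (log2 fold change 1.76), CDKN2B, a cell cycle inhibitor (0.85), CTGF, a matricellular protein (0.68), and TGFB1 itself (0.55) rose, and IL11 fell (-0.59). The risen members FN1, COL1A1 and COL4A1 are also on the list of matrix genes below. Among TGF-β family ligands, receptors and SMADs, 6 of 24 genes rose, 3 fell and 15 did not pass, with the same counts when adjusted over the list alone. FSTL3, which binds activins (0.71), the procollagen protease gene BMP1 (0.68), TGFB1 and the activin subunit gene INHBA (0.52) rose, and SMAD3 (-0.17) and TGFB2 (-0.34) fell. This list did not pass camera (adjusted p = 0.107) except with the GC trend removed (up, adjusted p = 0.0214, range 0.0145 to 0.348 over all settings).

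Output genes of the MEK/ERK pathway fell, with 13 of 26 members down, 3 up and 10 not past the test, and the same counts when adjusted over the list alone. The camera test gave adjusted p = 0.00805, and adjusted p = 0.411 with an estimated correlation. HBEGF (log2 fold change -1.08), FOSL1, an AP-1 subunit (-0.75), and the EGF receptor ligand gene EREG (-0.62) fell furthest. FOSL1 fell from 332 ± 13 to 197 ± 2.57 FPKM (SD, n = 2). The cyclin D1 gene CCND1 (-0.26) and the feedback genes SPRY4 (-0.45) and DUSP4 (-0.27) also fell. EPHA4 (0.69), KCNN4 (0.54) and MYC (0.35) rose. DUSP6, at 17 FPKM in shENG and 18.4 FPKM in shControl, SPRY2, ETV4 and ETV5 did not pass.

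Cell cycle genes fell by small amounts. Of 38 DNA replication and G1/S genes, 23 fell and 15 did not pass; adjusted over the list alone, 25 fell. The camera test of this list gave adjusted p = 6.29e-07, and adjusted p = 0.348 with an estimated correlation. PCNA, the sliding clamp of DNA polymerases, fell from 391 ± 20.1 to 253 ± 1.08 FPKM (SD, n = 2), a log2 fold change of -0.63. E2F8 (-0.60), CCNE2 (-0.41) and RRM2, a subunit of ribonucleotide reductase (-0.37), also fell, while MCM2, MCM3, MCM5 and MCM7 of the replicative helicase did not pass. Of 40 mitotic genes, 17 fell, 1 rose (CDC25B) and 22 did not pass; adjusted over the list alone, 20 fell and 1 rose. The mitotic list passed camera (adjusted p = 0.000259) but not with an estimated correlation (adjusted p = 0.348) or after quantile normalization (adjusted p = 0.128, with its median at -0.05), with a range of 4.40e-07 to 0.348 over all settings. CCNA2, the cyclin A2 gene (-0.46), the spindle checkpoint genes MAD2L1 (-0.37) and TTK (-0.36), and DLGAP5 (-0.27) fell.

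Replication-dependent histone genes also fell, with 4 of 9 members down and 5 not past the test, the same when adjusted over the list alone. The camera test gave adjusted p = 0.0282, and adjusted p = 0.348 with an estimated correlation. HIST1H2BC (-1.12), HIST2H2AC (-0.58), HIST1H2BD (-0.52) and HIST1H2BK (-0.35) were the members that fell, from levels of 18.8 FPKM or less. Histone genes have near-identical copies, and most of their transcripts lack poly(A) tails, so these levels are uncertain. The list's call also ended under fry (adjusted p = 0.0659), at 5 FPKM or more (0.108), with short noncoding RNA genes kept (0.0620) and without shControl 2 (0.0551), and its adjusted p ranged from 0.00367 to 0.348 over all settings.

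Genes of the structural extracellular matrix rose, with 22 of 29 tested members up and 7 not past the test, the same when adjusted over the list alone. Their median log2 fold change was 0.41, and camera gave adjusted p = 2.55e-10, and adjusted p = 0.348 with an estimated correlation. Fibrillar collagens COL3A1 (log2 fold change 1.52), COL5A2 (0.86), COL5A1 (0.70) and COL1A1 (0.49) rose, with basement membrane genes such as LAMA5 (0.77) and NID2 (0.75). EFEMP1, a fibulin, rose from 13.5 ± 0.08 to 27.3 ± 0.85 FPKM (SD, n = 2). SPARC, the list's most abundant member, rose from 240 to 335 FPKM. TNC (87.6 and 86.1 FPKM), COL6A3 and LUM did not pass. Of 7 fibroblast and mural cell markers, 4 also rose, among them PDPN (1.19) and PDGFRB (0.49), and 3 did not pass (camera adjusted p = 0.0841, fry adjusted p = 0.0141).

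Matrix remodelling and invasion genes rose with 10 of 24 members up, 3 down and 11 not past the test, the same when adjusted over the list alone. Camera gave adjusted p = 0.00972, adjusted p = 0.348 with an estimated correlation and adjusted p = 0.0594 over genes at 5 FPKM or more, with a range of 0.00332 to 0.348 over all settings. The collagenase gene MMP13 (0.92), PLAT, which encodes tissue plasminogen activator (0.86), MMP15 (0.66) and the collagen cross-linking enzyme gene LOX (0.64) rose. The urokinase receptor gene PLAUR (-0.47), TIMP3 (-0.21) and CTSB (-0.17) fell. Integrins and focal adhesion genes did not pass as a list (adjusted p = 0.275) except without genes holding a leading 7-base word (down, adjusted p = 0.0241, range 0.0241 to 0.879 over all settings). They had 4 of 25 up (ITGB8 at 0.64, TNS3 at 0.41, ITGA11 at 0.38 and ITGAV at 0.26), 7 down (FERMT2 at -0.35 and 6 others) and 14 not past the test. Adjusted over the list alone, 5 rose and 9 fell. Mesenchymal transition regulators and markers did not pass either (adjusted p = 0.337). There, 6 of 16 members rose, among them FN1 (0.55), SNAI2 (0.31), TWIST2 (0.36), PRRX1 (0.35) and CDH11 (0.35), 2 fell (VIM and AXL) and 8 did not pass; adjusted over the list alone, 6 rose and 3 fell.

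**Figure D3:**
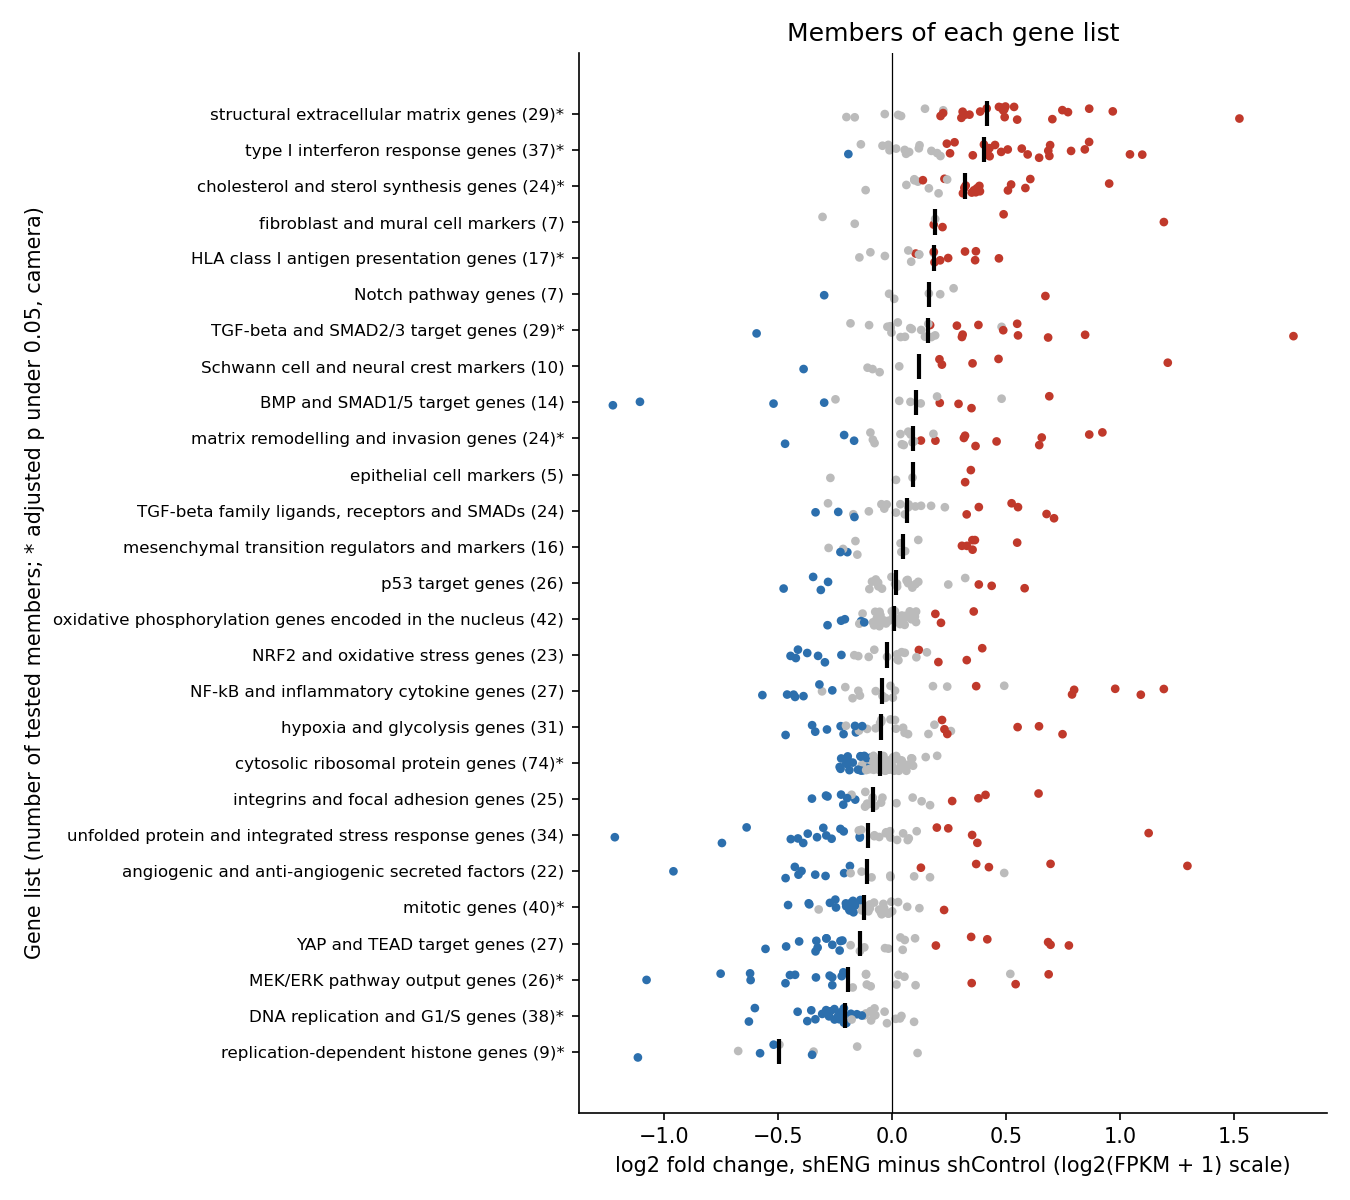
Log2 fold change (shENG minus shControl, log2(FPKM + 1) scale) of the tested members of 27 gene lists, 1 point per gene, in red where the gene rose, blue where it fell and grey where it did not pass, with black bars at list medians. Matrix genes (median 0.41), interferon response genes (0.40) and sterol synthesis genes (0.32) lie to the right, DNA replication genes (-0.21) to the left, and the ribosomal protein list (-0.05) turns to 0.03 under quantile normalization.

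Transcripts of secreted factors that act on blood vessels moved both ways. Of 22 angiogenic and anti-angiogenic factors, 9 fell, 5 rose and 8 did not pass, the same when adjusted over the list alone, and camera gave adjusted p = 0.381. FGF1 fell from 6.49 ± 0.54 to 2.85 ± 0.21 FPKM (SD, n = 2), VEGFA from 48.1 ± 0.89 to 34.5 ± 2.45 FPKM (SD, n = 2), and FGF2 (-0.43), PDGFA (-0.41) and VEGFC (-0.29) also fell. EDN1 (1.29) and CYR61, a matricellular protein (0.69), rose. THBS1, an inhibitor of vessel growth, was at 426 FPKM in shENG and 454 FPKM in shControl and did not pass. Of 27 YAP and TEAD target genes, 6 rose, 12 fell and 9 did not pass (adjusted p = 0.275); adjusted over the list alone, 6 rose and 13 fell. The widely used targets CYR61 and CTGF rose together with NUAK2 (0.77), NT5E fell (-0.56), and ANKRD1 did not pass.

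Type I interferon response genes rose, with 23 of 37 up, 1 down and 13 not past the test; adjusted over the list alone, 23 rose and 2 fell. Their median log2 fold change was 0.40, or 0.26 over genes at 5 FPKM or more, and camera gave adjusted p = 3.03e-08, and adjusted p = 0.348 with an estimated correlation. IFI27 rose from 9.80 ± 1.30 to 22.1 ± 2.83 FPKM (SD, n = 2), a log2 fold change of 1.10. OASL (1.04), IRF9, a subunit of the interferon-activated ISGF3 complex (0.86), the antiviral GTPase gene MX1 (0.84) and IFIT1 (0.78) rose, and PLSCR1 fell (-0.19). The RNA sensor gene DDX58, at 7.66 FPKM in shENG and 7.73 FPKM in shControl, did not pass. Genes of HLA class I antigen presentation rose as well, with 9 of 17 up and 8 not past the test; adjusted over the list alone, 10 rose and 1 fell. Camera gave adjusted p = 0.000395 for this list, and adjusted p = 0.348 with an estimated correlation. HLA-F (0.47), HLA-B (0.37), the peptide-loading gene TAPBP (0.36) and the immunoproteasome gene PSMB9 (0.32) rose, where HLA genes share reads with one another and are uncertain.

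NF-kB and inflammatory cytokine genes split. The chemokine gene CCL2 rose 2.29-fold, from 219 ± 0.98 to 501 ± 11.6 FPKM (SD, n = 2). TNF (log2 fold change 1.09), the pathway inhibitors NFKBIA (0.98) and TNFAIP3 (0.80) and IL6 (0.79) rose too. BIRC3 (-0.57), CSF3 (-0.46), RELB (-0.43), IL1B (-0.43) and CXCL5 (-0.39) fell. Of 27 members, 6 rose, 7 fell and 14 did not pass, and 7 rose and 7 fell adjusted over the list alone. These members had a median of -0.04 (-0.0899 without shENG 1 and -0.0748 without shControl 2) and a mean of 0.08 and fry pointed up, so these differ in sign, and camera gave adjusted p = 0.865.

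Genes of cholesterol and sterol synthesis rose, with 16 of 24 members up and 8 not past the test; adjusted over the list alone, 18 rose. With a median of 0.32, the list passed camera, which gave adjusted p = 1.52e-09, and adjusted p = 0.348 with an estimated correlation. TM7SF2 (log2 fold change 0.95), DHCR7 (0.61) and MSMO1 (0.58), enzymes of the later steps, rose, and so did HMGCS1 (0.51), the squalene epoxidase gene SQLE (0.38) and SREBF2, the transcription factor that drives the pathway (0.37). MSMO1 rose from 38.5 ± 1.49 to 58.2 ± 1.52 FPKM (SD, n = 2).

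Within the list of unfolded protein and integrated stress response genes, 15 of 34 members fell, 5 rose and 14 did not pass, the same when adjusted over the list alone. Those that fell included ATF4 (-0.14), the central transcription factor of the integrated stress response, and genes of amino acid transport and synthesis: SLC7A5 (-0.64), SLC3A2 (-0.44), SLC7A11 (-0.41), PSAT1 (-0.30) and ASNS (-0.29). DDIT4 (-1.22) and CHAC1 (-0.75), which degrades glutathione, fell further. ATF3 rose (1.12), and so did the endoplasmic reticulum chaperone genes HYOU1 (0.37), DNAJB9 (0.35) and PDIA4 (0.25), while HSPA5, at 182 FPKM in shENG and 176 FPKM in shControl, did not pass. Camera gave adjusted p = 0.0751 for the list, which was called down under fry (0.0238), with no filter on level (0.0198), without shENG 1 (0.0347), without shControl 1 (0.0447) and with the GC trend removed (0.0315), with a range of 0.0198 to 0.348 over all settings. Of 23 NRF2 and oxidative stress genes, 7 fell, 4 rose and 12 did not pass (adjusted p = 0.335), the same when adjusted over the list alone. OSGIN1 (-0.45), the quinone reductase gene NQO1 (-0.42) and SLC7A11 fell, and PGD of the pentose phosphate pathway rose (0.39).

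Hypoxia and glycolysis genes moved both ways, with 6 of 31 up, 9 down and 16 not past the test; adjusted over the list alone, 7 rose and 11 fell. The collagen prolyl hydroxylase gene P4HA2 (0.75), PFKFB4 (0.64) and ALDOC (0.55) rose, and VEGFA (-0.47) and the glucose transporter gene SLC2A1 (-0.35) fell. Their median was -0.05 (-0.0174 without shENG 1, -0.0291 without shENG 2 and 0.0304 after quantile normalization) and their mean was 0.01, fry pointed down, and camera gave adjusted p = 0.718. Of 42 nuclear genes of oxidative phosphorylation, 3 rose, 5 fell and 34 did not pass; adjusted over the list alone, 3 rose and 4 fell. NDUFA2 (0.36) and NDUFS3 (0.21) rose and NDUFS6 (-0.28) and NDUFV2 (-0.22) fell. The list's median was 0.0078 (-0.00418 without shENG 1, -0.00292 without shControl 1 and -0.0126 without shControl 2), its mean was -0.0017 and fry pointed up, and camera gave adjusted p = 0.805; after quantile normalization the list passed upward (median 0.09, adjusted p = 0.000917, range 0.000917 to 0.977 over all settings). Of 26 p53 target genes, 3 rose (PHLDA3 at 0.58, GADD45A at 0.44 and PLK2 at 0.38), 4 fell (PLK3 at -0.48, with AEN, MDM2 and PPM1D) and 19 did not pass (adjusted p = 0.698), the same when adjusted over the list alone. CDKN1A, the best known p53 target, was at 6.86 FPKM in shENG and 6.89 FPKM in shControl and did not pass. Of 7 Notch pathway genes, LFNG rose (0.67), HES1 fell (-0.30) and 5 did not pass (adjusted p = 0.275); adjusted over the list alone, 2 rose and 1 fell.

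Cytosolic ribosomal protein genes fell by small amounts as deposited, with 18 of 74 down and a median of -0.05 (-0.03 without shENG 1), and their median turned to 0.03 under quantile normalization. Camera gave adjusted p = 0.0119, and adjusted p = 0.348 with an estimated correlation. Adjusted over the list alone, 15 fell. RPL23A (-0.23), RPL6 (-0.23), RPL14 (-0.22) and RPS15A (-0.20) fell furthest, and 56 members did not pass. The call also ended under fry (adjusted p = 0.161), with a replicate block (0.0516), without an intensity trend (0.0752), at 5 FPKM or more (0.0780), without shENG 1 (0.202) and without shControl 1 (0.0582), with a range of 0.000141 to 0.348 over all settings.

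Markers of Schwann cells and neural crest were partly low in these cells. SOX10 and S100B were listed at 0 in all 4 libraries, and 10 of the list's 27 genes reached the level for testing. Of these, 5 rose, 1 fell and 4 did not pass, the same when adjusted over the list alone (adjusted p = 0.0902, and called up at 5 FPKM or more with adjusted p = 0.00883, range 0.00883 to 0.348 over all settings). The neural adhesion gene L1CAM rose from 9.83 ± 0.78 to 24.0 ± 0.48 FPKM (SD, n = 2), the progenitor marker NES (0.47) and the myelin gene PMP22 (0.35) rose, and NGFR fell (-0.39), from 1.31 FPKM. Among melanocyte lineage markers, 4 genes were tested and 0 passed in limma, also at an unadjusted p under 0.05. The most abundant of them, RAB27A, was at 19.1 FPKM in shENG and 19.4 FPKM in shControl, and MITF at 11.6 and 12 FPKM. The other lists of cell type markers were mostly below the level for testing. The fibroblast and mural cell markers THY1 (0.22) and MCAM (0.18) rose besides PDPN and PDGFRB; adjusted over the list alone, 4 of 7 rose and 1 fell. Of 5 epithelial markers, KRT8 (0.34) and KRT17 (0.32) rose and 3 did not pass (adjusted p = 0.287); adjusted over the list alone, 2 rose and 1 fell. In each of the endothelial and leukocyte lists 1 gene was tested and fell, ROBO4 (-0.27) and CD68 (-0.17), also when adjusted over the list alone. No mitochondrially encoded gene was in the table.

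Of the 27 lists tested with camera, 6 rose and 5 fell. With an estimated correlation 0 passed, where 2 lists, the interferon and sterol lists, had an unadjusted p under 0.05. That form of camera uses 2 residual degrees of freedom, so its losses do not by themselves point to correlation between genes. The interferon list's estimate was 0.0165, near the preset 0.01, yet its unadjusted camera p went from 3.37e-09 to 0.0319. The matrix list's estimate was higher, at 0.410. The fry test asks whether the genes of a list move one way on balance and does not compare them with other genes. It gave an adjusted p under 0.05 for 14 lists, 9 of which camera had also called; the others were the TGF-β family, mesenchymal, Schwann cell, stress response and fibroblast lists.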

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

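The tests without genes holding a leading 7-base word and with the GC content trend removed were chosen after the data were seen. ENG stayed lower in all settings, at a log2 fold change of -1.81 to -1.51 and an adjusted p of 5.69e-05 to 0.0221, and at -1.71 to -1.51 with 1 library left out. Against 1544 higher and 2043 lower genes among 11458 tested, no filter on level gave 770 and 1018 among 17730. Keeping short noncoding RNA genes gave 908 and 1285 among 11748, and limma treat at a fold of 1.5 gave 19 and 10. The 290 short noncoding RNA genes are too few for the adjustment alone to explain the loss of calls when they were kept. The cause of that loss was not tested. Leaving out 1 library gave 728 to 1043 higher and 1062 to 1402 lower genes, with fewer samples and with the lone library taken to vary like the others. The higher count moved over 1.5 times without shENG 1 (728), shENG 2 (806) and shControl 1 (1013), and the lower count without shENG 1 (1110), shENG 2 (1062) and shControl 2 (1332). Of the genes called both here and in a given setting, 0 changed direction, though settings that alter only the variance or the genes tested cannot change it. The genes called did change. Quantile normalization called 3127 genes, of which 2781 were shared with the 3587 called here. Removing the GC trend called 3389 of 10799 tested genes, of which 2741 were shared. The share of calls that were higher was 43.0%, 49.1% after quantile normalization and 46.1% after median centring. The shared replicate numbers did not pair the libraries (correlation of deviations -0.07), and a replicate block gave 1348 higher and 1744 lower genes, 6 lists up and 4 down, and ENG at -1.61.

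Lists called up were 6, 0 with an estimated correlation and 10 with fry; lists called down were 5, 0 with an estimated correlation, and 3 each at 5 FPKM or more and under quantile normalization. Treat was not applied to lists. With 1 library left out, lists up stayed at 6 and lists down at 4 to 5. Without word genes and with the GC trend removed, 11 of 11 list calls were kept. The mitotic list's median shrank from -0.12 to -0.07 when the GC trend was removed (camera adjusted p = 0.0140). Without word genes, integrins were gained (down, -0.11, camera adjusted p = 0.0241). With the GC trend removed, the TGF-β family list (up, 0.11, camera adjusted p = 0.0214) and the stress response list (down, -0.15, camera adjusted p = 0.0315) were gained. Medians that turned, of lists not called except the ribosomal one, were: under quantile normalization p53 targets (-0.00372), hypoxia and glycolysis (0.0304) and ribosomal proteins (0.0253); at 5 FPKM or more mesenchymal markers (-0.0609) and p53 targets (-0.00361); with the GC trend removed hypoxia and glycolysis (0.0025) and oxidative phosphorylation (-0.00409); without word genes NRF2 (0.0212). With 1 library left out, NRF2 ranged from -0.0814 to 0.0118 and turned without shENG 1 (0.0108) or shControl 1 (0.0118), oxidative phosphorylation ranged from -0.0126 to 0.0104 and turned without shENG 1 (-0.00418), shControl 1 (-0.00292) or shControl 2 (-0.0126), and p53 targets turned without shControl 2 (-0.000835). RAB27A, not called, turned from -0.02 to 0.00638 (quantile), 0.0811 (GC trend removed), and 0.00223 and 0.00345 (without shENG 1 or shControl 1), and ranged from -0.0487 to 0.00345 with 1 library left out. Other list medians that moved over 1.5 times with 1 library left out were BMP (0.0625 without shENG 1), NF-kB (-0.0899 without shENG 1, -0.0748 without shControl 2), hypoxia and glycolysis (-0.0174 without shENG 1, -0.0291 without shENG 2), ribosomal proteins (-0.0324 without shENG 1), Notch (0.0976 without shControl 1), angiogenic factors (-0.172 and -0.0551 without shControl 1 or 2), epithelial markers (0.0284 and 0.149, likewise), mesenchymal markers (0.029 without shENG 2, 0.103 without shControl 1), NRF2 (-0.0751 without shENG 2) and p53 targets (0.00687 without shENG 2). The cause of these turns and moves was not tested.

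Of 119 named genes past the threshold, 90 kept their call in every setting but treat in which they were tested, and 21 passed treat. Genes below 5 FPKM, with a leading word or without a matched transcript were not tested in some settings. The call ended in at least 1 other setting for 29: ALDOC, C15orf63, CD68, CDH11, CTGF, GADD45A, HES1, HIST1H2BC, HIST1H2BD, HIST1H2BK, HLA-F, ITGA11, KRT8, LFNG, MCAM, NDUFS3, NDUFS6, NDUFV2, NES, NGFR, OSGIN1, PRRX1, RNF5, ROBO4, RPL14, RPPH1, RPS15A, THY1 and TWIST2. Depth is unknown, and small changes were recovered less often in simulated data.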

Other observations

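The predictions for the word scan, library scaling and the trend on GC content and length were written before those tests were run, for patterns already seen; the search of named genes for the leading words and the setting without the genes that hold them were chosen after the scan was seen. The genes of the next 2 paragraphs lie outside the fixed lists or the rule for named genes, and were chosen after their values were seen.

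Transcripts of several secreted and surface proteins outside the lists rose. The complement gene C3 rose from 9.22 to 19.9 FPKM, the death ligand gene TNFSF10 (TRAIL) from 3.11 to 6.98 FPKM, and TNFSF18 from 0.611 to 2.36 FPKM. The neurotrophin gene NTF3 rose from 0.378 to 2.13 FPKM and GFRA1, a co-receptor for GDNF, from 9.28 to 20.4 FPKM. The surface protein genes CD24 (log2 fold change 1.16) and DPP4 (1.03) rose as well. Enhancers of procollagen processing, PCOLCE (1.02) and PCOLCE2 (0.97), and SULF2, which edits heparan sulfate (0.96), rose alongside the matrix list. The fatty acid desaturase genes FADS2 (0.96, from 31.8 to 63.0 FPKM) and SCD (0.71, from 109 to 179 FPKM) and the elongase gene ELOVL2 (0.88) rose, as did the metallothionein gene MT1F (1.04).

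Outside the lists, the autophagy gene ATG5 fell from 29.7 to 17.4 FPKM, and the ubiquitin ligase gene NEDD4L from 38.0 to 22.5 FPKM. ELTD1, an adhesion receptor known from endothelial cells, fell from 7.06 to 2.84 FPKM. Copies moved against each other for FAM45A, up from 1.00 to 2.94 FPKM, and FAM45B, down from 4.36 to 2.05 FPKM, while their sum was 5.36 ± 0.05 in shControl and 4.98 ± 0.71 in shENG (SD, n = 2). NME1-NME2, a readthrough of 2 genes, was at 7.30 and 15.8 FPKM in shENG and at 0.0519 and 0.0024 FPKM in shControl, while its sum with NME1 and NME2 was 1198 FPKM in shENG and 1295 FPKM in shControl.

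MAPRE1 fell 2.78-fold and C1D 2.2-fold, against 3.55-fold for ENG, and a candidate explanation is that the ENG hairpin also silenced transcripts that match its seed. Over 10445 genes, 3 words in the 3′ UTR went with lower fold changes, and all 3 occur in the ENG mRNA, where 14.8% of scanned words do: CAAGCAA (Bonferroni-adjusted p = 6.84e-05, 1258 genes, shift -0.04), GCAAGTA (0.00115, 655 genes, -0.05) and ACAAGCA (0.00210, 964 genes, -0.04). CAAGCAA and ACAAGCA overlap and lie at adjacent positions in ENG, so they may be largely 1 site. GCAAGTA lies elsewhere in ENG, so the seed of 1 hairpin cannot account for both GCAAGTA and the other 2 words. In addition, 1 of 10 simulated runs without a shifted word gave a false one. MAPRE1 holds 2 sites of GCAAGTA, C1D, NCEH1 and CMAS hold 1, and FGF1 and FAM111B hold the other 2 words, while IL24, ID1, DDIT4 and ID3, which fell further than C1D, and HBEGF hold none of the 3 words and 11 of 11 list calls were kept without the genes that do; other seed matches and indirect effects of silenced targets stay open. Silencing by the scrambled hairpin in the control cells would leave words in the genes that rose. The smallest Bonferroni p for such a word was 1. This argues against a shift as large as the simulated 0.06 in a word held by many genes. A weaker shift or a rarer word could be missed by the scan. The hairpin's sequence is not known, and loss of ENG itself stays open for every gene.

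The interferon response genes rose together (median 0.40, and 0.26 at 5 FPKM or more). Their list call ends in camera with an estimated correlation (adjusted p = 0.348), where 2 residual degrees of freedom leave little power. Library scaling is an unlikely source, since the list's lowest median under quantile normalization and median centring was 0.37. Fold changes rose with transcript GC content across genes (Spearman's rho 0.297), and the difference between the control libraries also tracked it (-0.210), but the list's median was still 0.35 after the trend on GC content and length was removed. Whether the response follows the loss of ENG, the hairpin or a difference between the transductions was not tested, and the number of hairpins is not given in the sources used here.

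Matrix genes, beside 4 of 7 fibroblast and mural cell markers, and sterol synthesis genes rose while DNA replication genes fell. All 3 list calls end in camera with an estimated correlation (adjusted p = 0.348), where 2 residual degrees of freedom leave little power. Library scaling left at least 70.6% of each list's median, and removing the trend on GC content and length left at least 78.7%, so neither accounts for the whole of the 3 shifts. A hypothesis is that they follow the loss of ENG, which these libraries cannot separate from other effects of the hairpin; another hairpin against ENG, or ENG expressed again in the shENG cells, would decide it and was not analysed here.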
